A study of Mus musculus with 18 samples.

How the data were processed

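Bulk RNA sequencing of retinal pigment epithelium (RPE) from mice at postnatal day 25, collected 1 h after light onset, gave 18 libraries in 5 groups. Per the labels, RNA was purified with a column kit, libraries were sequenced as paired ends on an Illumina instrument, and the tools named are STAR and DESeq2 against GRCm38 and mm10, without versions. The deposited values are a signal per gene in 2 tables, which the authors name normalized counts. The first table holds 6 C57BL/6, 3 Tyro3-/-V1 and 3 Mertk-/-V2Tyro3-/-V2 libraries, and the second, normalized separately, holds 3 WT129 and 3 Itgb5-/- libraries. Dividing each library by its own smallest step gave whole reads for 100% of the values above 0 in both tables, within a tolerance of 0.001 read, so a single size factor per library had been applied. The recovered totals were 14135502 to 30401422 reads per library, and the size factors were 0.541 to 1.197.

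The first table has 55573 lines, of which 240 without a gene name were left out, at most 0.0203% of a library's total. The second has 55421 lines, of which 3096 have no name and 3061 of these were named from their Ensembl identifier. Gene positions came from GENCODE M21 on GRCm38. No pair of replicates was a duplicate of another, since the chi-square per gene between replicates was 17 to 168.

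Each gene was tested with limma 3.58.1 in R 4.3.3 on log2 of the normalized count plus 1, with a mean-variance trend and robust shrinkage. Genes with a normalized count of at least 10 in at least 3 libraries were kept, 19711 in the first table and 18653 in the second. The model of the first table had a term for group and a term for the mark 23 in the sample names, which C57BL/6 replicates 1 to 3 and all mutant libraries carry and C57BL/6 replicates 4 to 6 do not. With that term, a log2 fold change against C57BL/6 rests on the 3 C57BL/6 libraries with the mark, while the spread is estimated from all 12 libraries with 8 residual degrees of freedom. Means and SD are given over all 6. The model of the second table had a term for group and 4 residual degrees of freedom. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes kept, with a threshold of 0.05.

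The 35 gene lists, for RPE functions, immune and stress responses, metabolism and the other cell types of the eye, were written before the data were examined, as were the models, the threshold and most of the alternative settings. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. A count of members is given over all genes tested and, in a second adjustment, adjusted over the list alone. Changes of Mertk, Tyro3 and Itgb5 were also tested by exact two-sided permutation, for which 3 against 3 libraries cannot go below p = 0.1 and 6 against 3 cannot go below 0.0119. Genes near Mertk, Tyro3 and Itgb5 were counted within 10 Mb and tested by Fisher's exact test. Another 3 marker lists, for ocular surface epithelium, lens and striated muscle, were added after the data had been seen.

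The genes named were chosen by a rule fixed in advance. It takes the targeted genes. It takes the 8 largest rises and 8 largest falls past the threshold with a mean of at least 50 in a group and no overlap between the groups, gene models and pseudogenes left out. It takes up to 3 members past the threshold from each list, and from a list past its own test without such a member, the 2 members of smallest p.

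The alternatives were pseudocounts of 0.5 and 10, no filter and a filter of 50, TMM rescaling, quantile normalization, array weights, replicate number as a block, only the compared groups, no term for the mark, only the marked libraries, a minimum absolute log2 fold change of 1, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, lists without shared members, windows of 5 and 20 Mb, and each library left out in turn. Of the genes tested against C57BL/6, edgeR called 121 in the libraries labelled Mertk-/-V2Tyro3-/-V2 and 9 in Tyro3-/-V1, and DESeq2 called 1725 and 131. Between these mutant groups edgeR called 35 and DESeq2 692, and for Itgb5-/- against WT129 the counts were 5 and 429. Covariates for neural retina, ocular surface and microglia scores, a term for sex in the second table, and leaving out the 2 libraries at the ends of the first component were added after seeing the data.

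The steps were tested on simulated data with the measured depths and spread and with genes independent of each other. Of 100 genes of mean at least 50 changed 2-fold, 35 to 57 were recovered across the 4 comparisons, and of 100 changed 4-fold, 86 to 91. There were 4 to 12 false calls among 18255 to 19350 genes. A list of changed genes had p of at most 8.64e-38. Of 100 unchanged lists, 3, 1, 3 and 3 had p below 0.05. The first of these 100 had p of 0.0153, 0.525, 0.00213 and 0.552, below 0.05 in 2 of 4 comparisons. These lists were random draws of independent genes, so they do not give the rate of false calls for lists whose genes vary together. In the first table the estimated correlation was 0.412 for the type I interferon list and 0.908 for the rod list. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, the block used statmod 1.5.0, and plots were drawn with matplotlib 3.10.9. Intervals of fold changes come from the limma fit and rest on the spread between libraries. The floor of 3 reads covers counting error only, and reads carry no molecular identifiers. Splicing, exon coverage and raw reads were not analysed here, so a deletion of part of a gene could not be seen.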

Results

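Messenger RNA was measured in the RPE, the pigmented cell layer behind the photoreceptors that takes up their shed outer segments. The groups were C57BL/6 with 6 libraries and Tyro3-/-V1, Mertk-/-V2Tyro3-/-V2, WT129 and Itgb5-/- with 3 each. Mertk and Tyro3 encode receptor tyrosine kinases of the same family, and Itgb5 encodes an integrin beta chain; Mertk and the integrin act in outer segment uptake. The comparisons ask how loss of these receptors changes RPE transcripts soon after light onset, when uptake peaks.

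C57BL/6 replicates 1 to 6 held 30191733, 23414164, 27556358, 14135502, 18263609 and 15517489 reads. Tyro3-/-V1 replicates 1 to 3 held 26962515, 30154428 and 25073575 reads, and the Mertk-/-V2Tyro3-/-V2 replicates held 25385952, 30401422 and 28489661. The WT129 replicates held 21767887, 24519972 and 22280556 reads, and the Itgb5-/- replicates held 26287189, 21871157 and 25242322. The first component held 47.3% of the variance in the first table, with C57BL/6 replicate 1 at −75.1 and Mertk-/-V2Tyro3-/-V2 replicate 3 at 95 as its ends. In the second table it held 37.1%. Fold changes against C57BL/6 come from the fit, which compares with the 3 C57BL/6 libraries that carry the mark 23, so they differ from the ratio of the means over all 6.

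Tyro3 (GRCm38 chromosome 2, 119797733 to 119818104) fell in both mutant groups of the first table. C57BL/6 had 3398 ± 514 normalized counts (SD, n = 6), and Tyro3-/-V1 had 1292 ± 122 (SD, n = 3), a log2 fold change of −1.55 ± 0.12 (SE, limma adjusted p = 0.000935). The libraries labelled Mertk-/-V2Tyro3-/-V2 had 1705 ± 244 (SD, n = 3), a log2 fold change of −1.16 ± 0.12 (limma adjusted p = 0.0101). All 3 mutant libraries lay below all 6 C57BL/6 libraries in each case, and the exact permutation p was 0.0119, the smallest that 84 splits can give. Without C57BL/6 replicate 1 or 2 the adjusted p in the libraries labelled Mertk-/-V2Tyro3-/-V2 was 0.0605 or 0.0599, and over all alternatives it ranged up to 0.131.

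Mertk (chromosome 2, 128698956 to 128802894) did not differ detectably in the libraries labelled Mertk-/-V2Tyro3-/-V2. They had 3409 ± 631 normalized counts (SD, n = 3) beside 3202 ± 454 in C57BL/6 (SD, n = 6). The log2 fold change was −0.06, with a 95% interval of −0.47 to 0.35 (limma adjusted p = 0.855). A total per gene cannot see a deletion of part of a transcript, so the groups are named here by their labels.

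Itgb5 (chromosome 16, 33829665 to 33949338) fell from 3622 ± 589 normalized counts in WT129 to 1199 ± 58 in Itgb5-/- (SD, n = 3 each), 33.4% of the control level. The log2 fold change was −1.58 ± 0.14 (SE, limma adjusted p = 0.0176), and the exact permutation p was 0.1, the smallest that 3 against 3 can give. It was lower in 3 of 3 libraries. The adjusted p was 0.0925 without WT129 replicate 1, 0.0905 without WT129 replicate 3, and 0.147, 0.173 and 0.257 without Itgb5-/- replicate 1, 2 or 3, and ranged up to 0.362 over all alternatives. In Itgb5-/-, Mertk (log2 0.10, limma adjusted p = 0.908) and Tyro3 (log2 0.28, adjusted p = 0.742) were within the spread. Itgb5 did not pass with limma in the libraries labelled Mertk-/-V2Tyro3-/-V2 (log2 −0.13, adjusted p = 0.449) or in Tyro3-/-V1 (−0.19, 0.825). Each of these mutant libraries lay below the 3 marked C57BL/6 libraries (exact permutation p = 0.1 in each group, the smallest possible). Over all 6 C57BL/6 libraries the exact permutation p was 0.9881 and 0.619.

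**Figure D1:**
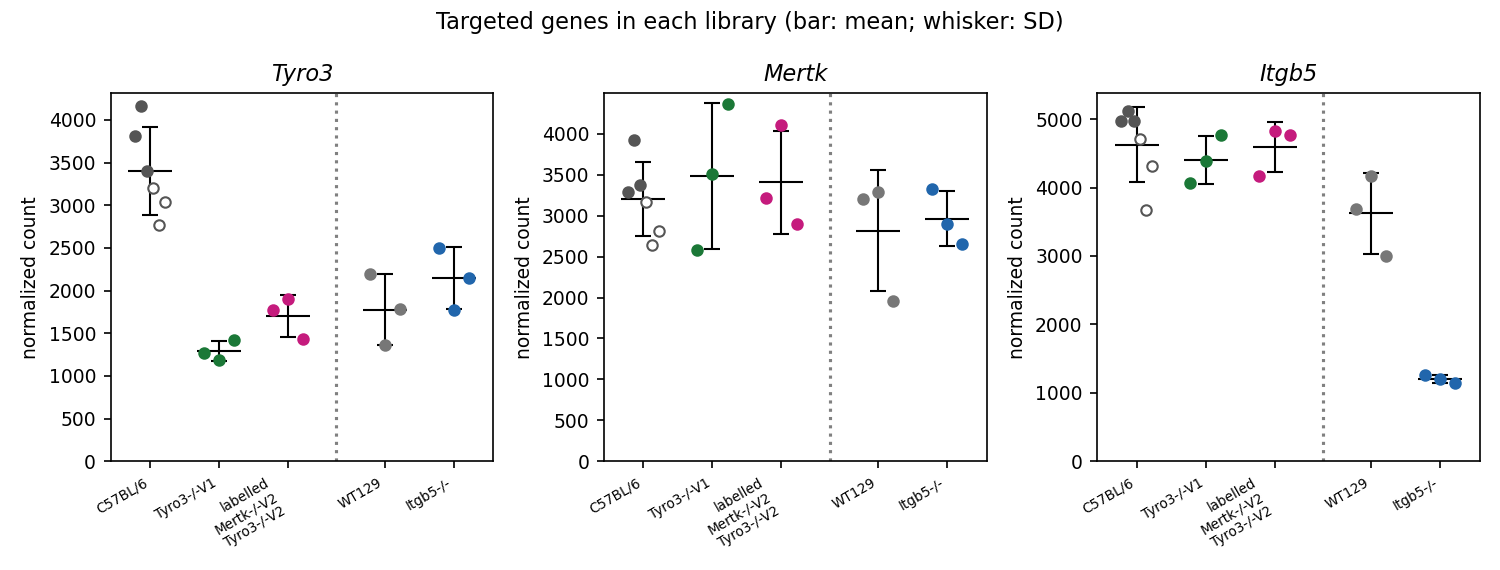
Normalized counts of Tyro3, Mertk and Itgb5 in each of the 18 libraries (points) by group, with the mean and SD; open points are C57BL/6 libraries without the mark 23, and the dotted line separates the tables normalized separately. Tyro3 lies at 1292 in Tyro3-/-V1 and 1705 in the libraries labelled Mertk-/-V2Tyro3-/-V2 beside 3398 in C57BL/6, and Mertk at 3409 beside 3202.

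The libraries labelled Mertk-/-V2Tyro3-/-V2 had higher interferon-induced and complement transcripts than C57BL/6. Cmpk2, a nucleotide kinase induced by interferon, rose 2.98-fold from 153 ± 22.8 (SD, n = 6) to 418 ± 22.8 normalized counts (SD, n = 3; limma adjusted p = 0.0101). Ifit1, which binds foreign RNA, rose 3.55-fold (log2 1.83 ± 0.24, adjusted p = 0.0197), and Ifi44, an interferon-induced gene, rose 6.5-fold (log2 2.70 ± 0.38, adjusted p = 0.025). C4b, a complement component cleaved in the classical pathway, rose 4.45-fold from 1123 ± 263 (SD, n = 6) to 4076 ± 1118 (SD, n = 3; adjusted p = 0.0104). In each of these 4 genes all 3 mutant libraries lay above all 6 C57BL/6 libraries.

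Of the 36 measured genes of the type I interferon list, 7 rose, 0 fell and 29 did not pass over all genes, while 23 were higher and 0 lower when adjusted over the list alone. Mx1 (log2 2.38) and Oas1a (2.08), both antiviral effectors, were among those that rose. The list's median log2 fold change was 0.85 (camera adjusted p = 2.99e-11; adjusted p = 0.628 with an estimated correlation; fry adjusted p = 0.0392). The mean score of the list was 9.77, 9.44 and 8.70 in Mertk-/-V2Tyro3-/-V2 replicates 1 to 3, beside 8.10 to 8.47 in C57BL/6 and 8.24 to 8.64 in Tyro3-/-V1. Of 35 interferon gamma and antigen presentation genes 2 rose, Iigp1 (log2 1.93) and Irgm2 (1.08), GTPases that act against intracellular pathogens; the list did not pass (median 0.00, mean 0.37, camera adjusted p = 0.0974). Adjusted over that list alone, 10 of its genes were higher and 0 lower. Apol9a (log2 2.44) also rose.

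Of 19 complement genes 5 rose and 0 fell, and 11 were higher and 1 lower adjusted over the list alone. Beside C4b these included Cfi, a protease that inactivates complement (log2 2.00 ± 0.34, adjusted p = 0.0362), and Cd59a, an inhibitor of the lytic pore (log2 1.00 ± 0.12, adjusted p = 0.0119). The list's median was 0.65 (camera adjusted p = 1.5e-06; adjusted p = 0.268 with an estimated correlation; fry adjusted p = 0.00412). Markers of microglia and macrophages were higher in the same libraries: of 32 measured, 2 rose, C1qc (log2 0.93) and Ctss (0.78), and the list's median was 0.48 (camera adjusted p = 1.09e-05; adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 10 were higher and 1 lower.

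Of 23 genes of JAK-STAT3 signalling and retinal stress 3 rose: Socs3, a feedback inhibitor of cytokine signalling (log2 1.06 ± 0.16, adjusted p = 0.0268), Cebpd, a transcription factor of the acute phase response (log2 1.28 ± 0.18, adjusted p = 0.0268), and the growth factor Fgf2 (log2 1.70 ± 0.30, adjusted p = 0.0364). The list as a whole did not pass (median 0.03, camera adjusted p = 0.127), while 7 were higher and 0 lower adjusted over the list alone. Csf1, a macrophage growth factor in the list of cytokines (log2 0.58), and Gsdme, a pore-forming protein in the cell death list (0.94), rose as the single members of their lists, and neither list passed. Lrrc2 (log2 2.70) and Chrna3, a nicotinic receptor subunit (2.03), also rose.

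RPE genes of the visual cycle were lower. Rpe65, the isomerase that regenerates the visual chromophore, fell 2.88-fold from 80835 ± 16276 normalized counts (SD, n = 6) to 32918 ± 9735 (SD, n = 3; log2 −1.53 ± 0.22, adjusted p = 0.0268), in 3 of 3 libraries. Of 18 visual cycle genes 1 fell over all genes, and 9 were lower and 1 higher adjusted over the list alone (median −0.59, camera adjusted p = 0.000401; adjusted p = 0.628 with an estimated correlation). Of 28 genes of RPE identity and transport 1 fell, Enpp2, which makes lysophosphatidic acid (log2 −1.24 ± 0.20, adjusted p = 0.0348), and 10 were lower and 3 higher adjusted over the list alone. That list's median was −0.39 (camera adjusted p = 0.000673; adjusted p = 0.628 with an estimated correlation; 0.0865 after quantile normalization). The 16 melanin synthesis genes had a median of 0.23, with 0 past the limma threshold over all genes or adjusted over the list alone (camera adjusted p = 0.193).

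Falls included Ins2, an insulin gene (log2 −4.57 ± 0.47, adjusted p = 0.0101), Rab37, a GTPase of secretory vesicles (−3.05 ± 0.31, adjusted p = 0.0101), and Sfrp5, a secreted Wnt antagonist (−1.70 ± 0.19, adjusted p = 0.0101). The fatty acid receptor Ffar2 (−2.13), the proton pump subunit Atp6v1e2 (−2.00), the lysophosphatidic acid receptor Lpar3 (−1.69) and Stox1 (−1.55) also fell. Of 27 phagocytosis genes 2 fell, Tyro3 and the kinase Src (log2 −0.74), and the list did not pass (median −0.11, camera adjusted p = 0.12). Srebf1, a regulator of lipid synthesis (−0.63), Ccnd1, a cyclin (−0.60), and Hist1h1c, a linker histone (−0.62), fell as the single members of their lists past the threshold.

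**Figure D2:**
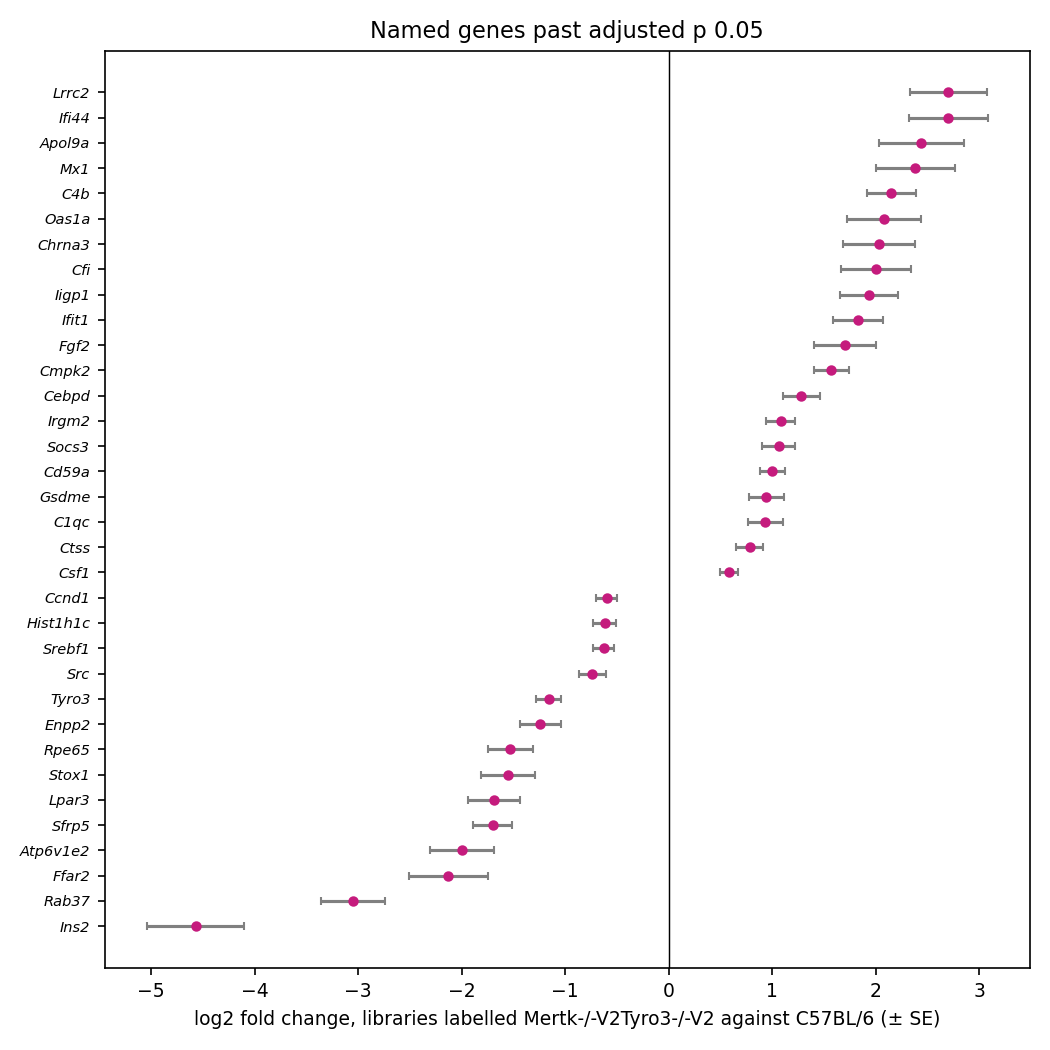
Log2 fold change and SE of the named genes past the threshold in the libraries labelled Mertk-/-V2Tyro3-/-V2 against C57BL/6 (3 and 6 libraries), largest rise to largest fall. Ifi44 rose by 2.70 and Ins2 stands at −4.57.

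Markers of neural retina and other tissues differed between the same libraries. The medians were 1.55 for 25 inner retinal neuron markers (camera adjusted p = 1.09e-05; adjusted p = 0.628 with an estimated correlation), 1.24 for 14 cone markers (7.93e-05; 0.628 with an estimated correlation) and 0.92 for 28 rod markers (0.00183; 0.704 with an estimated correlation), with 0 members past the limma threshold. Without the 2 libraries at the ends of the first component the median was −0.14 for rod markers (adjusted p = 0.104) and 0.30 for inner retinal markers (0.072), and neither passed. The rod call also ended with no term for the mark (median 0.07, adjusted p = 0.605), array weights (0.39, 0.235) or the ocular surface covariate (0.29, 0.833), and without C57BL/6 replicate 1 (adjusted p = 0.262) or Mertk-/-V2Tyro3-/-V2 replicate 3 (0.184). Endothelial markers (median 0.74, adjusted p = 4.88e-05), fibroblast and mural markers (0.48, 0.0325) and matrix genes (0.32, 0.0138) were higher, each with adjusted p = 0.628 with an estimated correlation. The fibroblast call ended without C57BL/6 replicate 1 (adjusted p = 0.0848) or 4 (0.0586) or Mertk-/-V2Tyro3-/-V2 replicate 1 (0.0507) or 2 (0.123), with only the compared groups (0.0538), with the marked libraries alone (0.063) and with the replicate block (0.0803), and the matrix call without Mertk-/-V2Tyro3-/-V2 replicate 2 (0.117).

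Lower lists were replication-dependent histones (11 measured, 9 lower adjusted over the list alone; median −0.66, adjusted p = 1.09e-05; adjusted p = 0.268 with an estimated correlation; fry adjusted p = 0.00694) and cell cycle genes (median −1.02, adjusted p = 1.68e-06; adjusted p = 0.628 with an estimated correlation). The mean cell cycle score was 9.03 in marked and 7.73 in unmarked C57BL/6 libraries, and 7.96 in those labelled Mertk-/-V2Tyro3-/-V2. Ocular surface epithelium markers, a list added after the data had been seen, had a median of −1.38 and scores of 12.92, 11.7 and 11.73. A link between these 2 lists was not tested. Unfolded protein response genes (median −0.24, adjusted p = 0.000477) and fatty acid oxidation genes (−0.22, 0.000885) were lower, each with adjusted p = 0.628 with an estimated correlation. Nuclear respiratory chain genes (−0.14, 0.000477) and NRF2 and metallothionein genes (−0.20, 0.0109) had adjusted p = 0.704 with an estimated correlation. The respiratory chain call ended after quantile normalization (−0.05, 0.257) and with the retina (−0.01, 0.472) or ocular surface covariate (−0.02, 0.116). The fatty acid oxidation and NRF2 calls also ended with the retina covariate, and the NRF2 call with the ocular surface covariate. The NRF2 call ended after quantile normalization (−0.09, 0.297), without Mertk-/-V2Tyro3-/-V2 replicate 3 (0.0748), without the 2 libraries at the ends (−0.08, 0.226) and with no term for the mark (−0.06, 0.0964). Among their members, Mt1 had log2 −0.99 (adjusted p = 0.0503) and Nqo1 −1.02 (0.0941). The lists for Muller glia (median 0.81, adjusted p = 0.0688), erythroid cells (−0.38, 0.12), sex-linked transcripts (0.12, 0.35), glycolysis (0.11, 0.304), mitochondrial transcripts (−0.12, 0.185), cholesterol synthesis (0.06, 0.648), lysosome (−0.05, 0.231), the circadian clock (−0.01, 0.664), lymphocytes and granulocytes (−0.01, 0.952), cytokines and chemokines (0.03, 0.657) and cell death (−0.06, 0.929) did not pass. Of the 16 Muller glia markers, 8 were higher and 3 lower adjusted over the list alone. Median and mean differed in sign for melanocyte and Schwann cell markers (0.14 and −0.03, adjusted p = 0.952), lipid efflux (−0.09 and 0.01, 0.185) and immediate early genes (−0.04 and 0.16, 0.865).

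Markers of lens, a list added after the data had been seen, had a median of 1.58, with scores of 13.53 ± 1.18 (SD, n = 3) beside 11.26 ± 1.31 in C57BL/6 (SD, n = 6).

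In all, 54 genes rose and 49 fell in the libraries labelled Mertk-/-V2Tyro3-/-V2 against C57BL/6, of 19711 tested with limma, and 4324 (21.9%) had an unadjusted p below 0.05. edgeR called 121 (54 higher, 67 lower) and DESeq2 1725 (1125 higher, 600 lower). Without Mertk-/-V2Tyro3-/-V2 replicate 2 limma called 33 higher and 101 lower, so the balance of directions depended on the setting. The limma count rested on few libraries: it was 0 without C57BL/6 replicate 1 or 2 (2721 and 3069 at an unadjusted p below 0.05; edgeR and DESeq2 were not run on those subsets), 6, 50 and 19 without replicate 3, 5 or 6, and 10 and 39 without Mertk-/-V2Tyro3-/-V2 replicate 1 or 3. Over the 9 fits that left out 1 library, Tyro3, Ins2, Rab37, Sfrp5 and C4b passed in 7, Cmpk2 and Cd59a in 6, Ifit1, Ifi44, Irgm2 and Lrrc2 in 5, and the other named genes in 1 to 4. The count was 13 without the 2 libraries at the ends of the first component, 11 with the marked libraries alone, and 0 with the microglia score as a covariate (2844 unadjusted). Of 35 lists, 9 were higher and 8 lower at the preset correlation, against 0 with an estimated correlation (2 unadjusted) and 3 with fry.

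**Figure D3:**
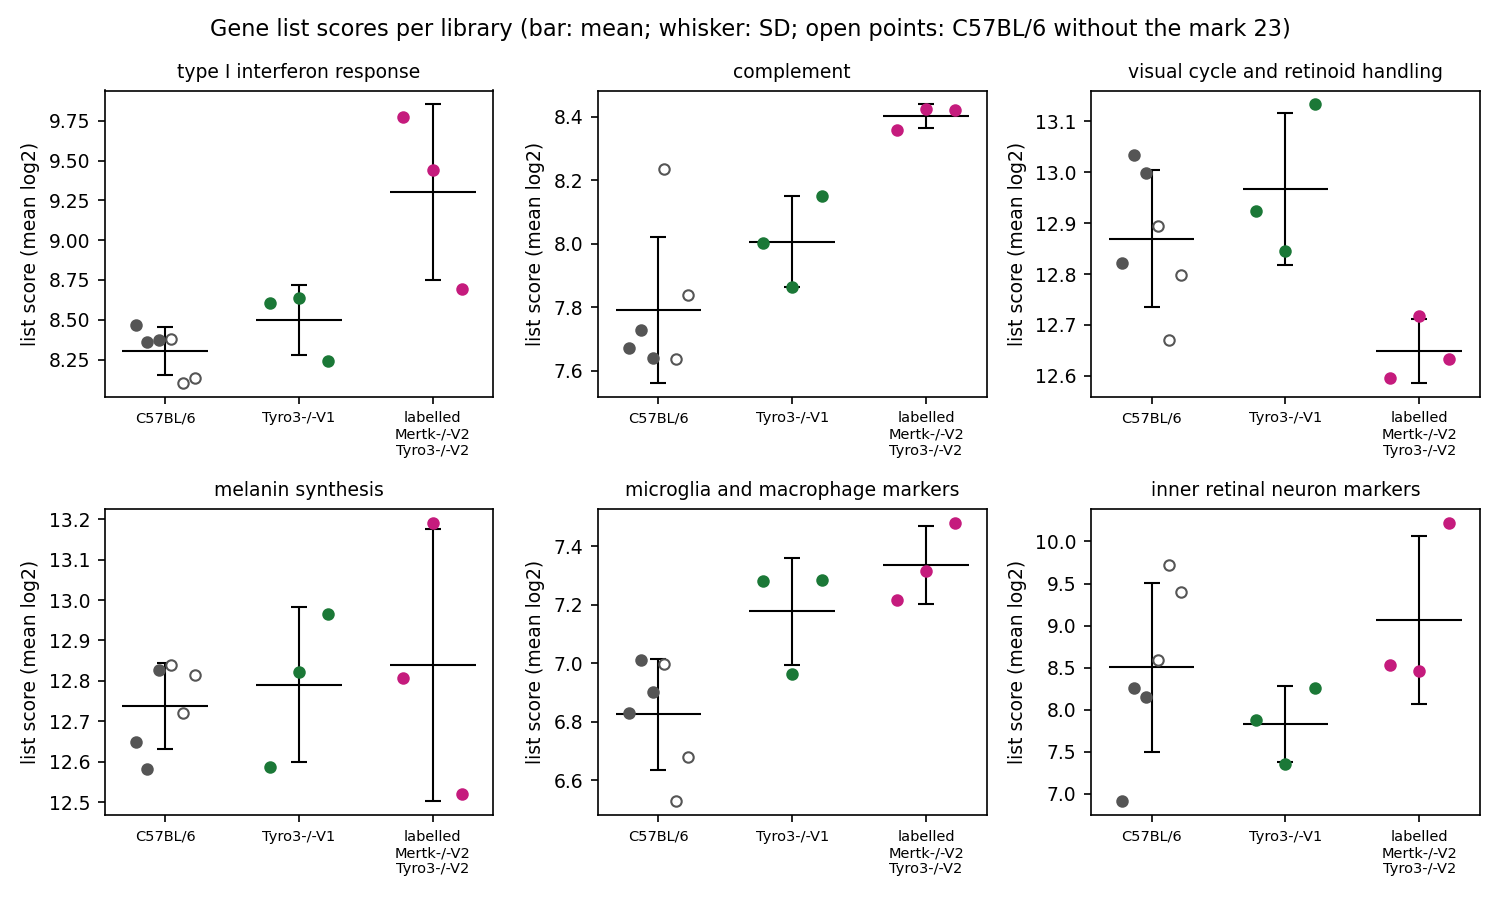
Mean log2 score of 6 gene lists in each library of the first table (points), with the mean (bar) and SD (whisker) of each group. The interferon score is 9.77, 9.44 and 8.70 in the libraries labelled Mertk-/-V2Tyro3-/-V2 and 8.10 to 8.47 in C57BL/6.

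Tyro3-/-V1 asks what loss of Tyro3 alone changes against C57BL/6. Few genes passed, and several lay on chromosome 2. Eif3j2 (chromosome 18, 43475418 to 43477796), a copy of a translation initiation factor gene, rose 8.52-fold from 57.9 ± 14.8 normalized counts (SD, n = 6) to 420 ± 28.4 (SD, n = 3; log2 3.09 ± 0.26, adjusted p = 0.00101). Its near-identical parent gene Eif3j1 (chromosome 2, 122028546 to 122056598) fell from 949 ± 90.1 to 517 ± 48.3 (log2 −0.94 ± 0.11, adjusted p = 0.0105). The sum of both was 1007 ± 92 in C57BL/6 and 937 ± 76 in Tyro3-/-V1. Lum, a proteoglycan of the collagen matrix (log2 1.23 ± 0.17, adjusted p = 0.0358), and Mzt1, a component of microtubule nucleation (0.46 ± 0.06, adjusted p = 0.0358), also rose.

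The other genes past the threshold, named after their values were seen, were Gm3650 (log2 4.33), Pcna-ps2 (3.88), Tgm3, a transglutaminase (3.08), and AA467197 (−4.64 ± 0.50, adjusted p = 0.00755). With Tyro3 this made 6 higher and 3 lower of 19711 tested with limma, with 1322 at an unadjusted p below 0.05; edgeR called 9 and DESeq2 131. The count was 4 without C57BL/6 replicate 1 or 3 or Tyro3-/-V1 replicate 3, and 3 without Tyro3-/-V1 replicate 2. Tyro3 and Eif3j2 passed without each library in turn, Eif3j1 in 4 of 9 such fits, Lum in 1 and Mzt1 in 0, and over all alternatives the adjusted p ranged up to 0.021 for Tyro3 and Eif3j2, 0.182 for Eif3j1, 0.311 for Lum and 0.325 for Mzt1. Array weights gave 4354 calls with a fit that did not converge.

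Cholesterol synthesis genes were lower and endothelial markers higher in Tyro3-/-V1 than in the marked C57BL/6 libraries. The cholesterol score was 10.2 to 10.64 in Tyro3-/-V1, beside 10.78 to 10.92 in marked and 10.18 to 10.59 in unmarked C57BL/6 libraries. For endothelial markers it was 8.36 to 9.58 beside 7.87 to 8.56 and 8.64 to 9.27, so both scores overlapped the unmarked libraries. Both lists still passed the camera test with no term for the mark. Of 24 cholesterol genes, 0 passed with limma over all genes and 18 were lower adjusted over the list alone, with a median of −0.43 (camera adjusted p = 3.49e-17; adjusted p = 0.351 with an estimated correlation). Mvd, a decarboxylase of the pathway, stood at −0.71 ± 0.16 (adjusted p = 0.331) and Lss, which cyclizes squalene epoxide, at −0.52 ± 0.11 (adjusted p = 0.297). Of 19 endothelial markers 14 were higher adjusted over the list alone, with a median of 0.88 (camera adjusted p = 3.21e-15; adjusted p = 0.351 with an estimated correlation), among them Erg (0.89 ± 0.18, adjusted p = 0.285) and Cd34 (0.79 ± 0.20, adjusted p = 0.374). Of 17 fibroblast and mural markers 1 rose, Lum, and 4 were higher adjusted over the list alone (median 0.54, camera adjusted p = 1.47e-05; adjusted p = 0.275 with an estimated correlation).

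Smaller shifts went up in microglia and macrophage markers (median 0.28, adjusted p = 2.76e-05; adjusted p = 0.505 with an estimated correlation), complement (0.26, 0.000212), matrix genes (0.23, 0.000346) and mitochondrial transcripts (0.13, 0.00234; adjusted p = 0.808 with an estimated correlation). Complement and matrix genes had adjusted p = 0.351 with an estimated correlation. The complement and mitochondrial calls ended with the microglia score as a covariate. Cell cycle genes were lower (−0.82, adjusted p = 4.66e-06; adjusted p = 0.752 with an estimated correlation), as were unfolded protein response genes (−0.18, 4.48e-05), erythroid markers (−0.64, 0.000212) and histones (−0.19, 0.0241), with adjusted p = 0.505 with an estimated correlation. Ocular surface epithelium markers, a list added after the data had been seen, had a median of −0.65, and a link with the cell cycle genes was not tested. The histone call ended with no filter (0.0606), with the marked libraries alone (0.0954) and without C57BL/6 replicate 2 (0.441) or 6 (0.0827) or Tyro3-/-V1 replicate 1 (0.235), and the mitochondrial and cell cycle calls without Tyro3-/-V1 replicate 3 (0.0815 and 0.0561). With no term for the mark, against all 6 C57BL/6 libraries, none of the 5 lists of cell cycle (median −0.08, adjusted p = 0.635), unfolded protein (−0.03, 0.19), erythroid (0.11, 0.571), histone (−0.07, 0.336) and mitochondrial genes (−0.01, 0.486) passed. The type I interferon list did not pass (median 0.04, adjusted p = 0.442), nor did the visual cycle list (−0.01, 0.995). Of 35 lists 6 were higher and 5 lower, 19 passed without Tyro3-/-V1 replicate 3, and 0 passed with an estimated correlation (4 unadjusted) or with fry (6 unadjusted).

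Beside Tyro3 itself, 217 tested genes lay within 10 Mb of it, and 2 of these passed in Tyro3-/-V1, against 6 of 19260 elsewhere (Fisher's exact p = 0.00331, Benjamini-Hochberg 0.00993, odds ratio 29.8). Among the 50 genes of smallest p, 13 lay within 10 Mb of Tyro3 where 0.6 were expected by their share. In the libraries labelled Mertk-/-V2Tyro3-/-V2 against C57BL/6, 1 of 217 passed (exact p = 1) and 0 of the 50 genes lay there. Within 10 Mb of Mertk, a window that overlaps that of Tyro3, 3 of 241 passed in Tyro3-/-V1 (Fisher's exact p = 0.0001, odds ratio 48.4), 1 of 241 in the libraries labelled Mertk-/-V2Tyro3-/-V2 (exact p = 1) and 6 of 241 between the mutant groups (exact p = 8.03e-07).

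**Figure D4:**
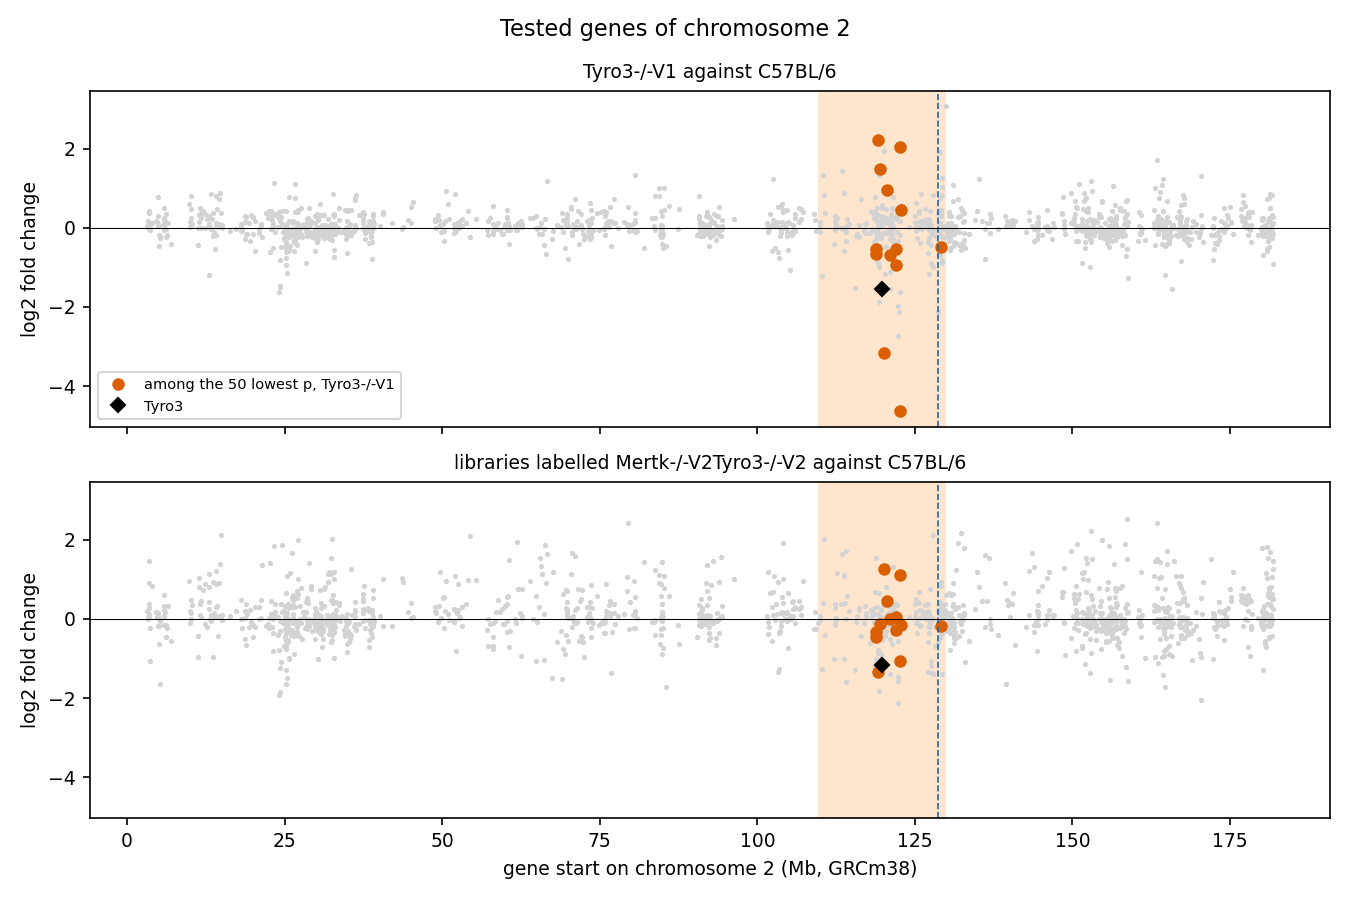
Log2 fold change against C57BL/6 of tested genes by their start on chromosome 2 (GRCm38), in Tyro3-/-V1 and in the libraries labelled Mertk-/-V2Tyro3-/-V2; shading marks 10 Mb either side of Tyro3 (diamond), the dashed line marks Mertk, and orange marks the 13 genes near Tyro3 among the 50 of smallest p in Tyro3-/-V1. Their median absolute log2 fold change is 0.94 in Tyro3-/-V1.

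The direct contrast of the libraries labelled Mertk-/-V2Tyro3-/-V2 with Tyro3-/-V1 shows which of the changes differ between the mutant groups. Ifit1 (log2 1.96 ± 0.24, adjusted p = 0.0138), Cmpk2 (1.20 ± 0.17, adjusted p = 0.026) and C4b (1.73 ± 0.24, adjusted p = 0.026) were higher than in Tyro3-/-V1 in 3 of 3 libraries. Rpe65 was lower, at 32918 ± 9735 beside 89720 ± 20048 normalized counts (SD, n = 3 each; log2 −1.46 ± 0.22, adjusted p = 0.0379). Ins2 (−3.99 ± 0.47, adjusted p = 0.0138), Rab37 (−2.90 ± 0.31, adjusted p = 0.0086), Sfrp5 (−1.43), Psd3 (−1.30) and Sostdc1, a secreted antagonist of bone morphogenetic proteins (−1.50), were lower, and Sulf2, a heparan sulfatase (1.47), and Kcnab1, a potassium channel subunit (1.35), higher. Eif3j2 was lower (−3.29 ± 0.26, adjusted p = 0.000817) and Eif3j1 higher (0.99 ± 0.11, adjusted p = 0.0086), and Gchfr, a regulator of tetrahydrobiopterin synthesis near Tyro3, was lower (−3.54 ± 0.43, adjusted p = 0.0142). Tyro3 itself did not pass (log2 0.39 ± 0.12, adjusted p = 0.256).

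The interferon list was higher than in Tyro3-/-V1 (2 of 36 rose, 23 higher adjusted over the list alone; median 0.74, camera adjusted p = 4.86e-14; adjusted p = 0.465 with an estimated correlation), as was complement (1 rose, C4b; median 0.31, 0.000263; adjusted p = 0.465 with an estimated correlation). Cholesterol synthesis was higher (0 rose with limma over all genes, 16 higher adjusted over the list alone; median 0.51, 2.48e-11; adjusted p = 0.465 with an estimated correlation). Visual cycle genes were lower (1 fell, Rpe65; 11 lower adjusted over the list alone; median −0.55, 2.82e-05; adjusted p = 0.465 with an estimated correlation), as were RPE identity genes (14 lower and 2 higher adjusted over the list alone; −0.39, 2.82e-05; adjusted p = 0.625 with an estimated correlation). Inner retinal (1.33, 3.95e-07) and cone markers (1.01, 2.43e-05) were higher in the same libraries, each with adjusted p = 0.625 with an estimated correlation.

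Fatty acid oxidation (−0.30, 1.33e-06; adjusted p = 0.625 with an estimated correlation), mitochondrial transcripts (−0.25, 5.04e-05; adjusted p = 0.659 with an estimated correlation), histones (−0.43, 0.000341; adjusted p = 0.465 with an estimated correlation) and the respiratory chain (−0.12, 5.71e-05; adjusted p = 0.806 with an estimated correlation; 0.102 without Tyro3-/-V1 replicate 1) were lower. Glycolysis (0.26, 0.00688; adjusted p = 0.731 with an estimated correlation; 0.218 without Mertk-/-V2Tyro3-/-V2 replicate 3, 0.241 without the 2 libraries at the ends) was higher. Rod markers (0.44, 0.043; adjusted p = 0.916 with an estimated correlation) passed, but not without Mertk-/-V2Tyro3-/-V2 replicate 3 (−0.06, 0.75) or Tyro3-/-V1 replicate 1 or 2 (0.229 and 0.112). Microglia markers (0.26, 0.0314; adjusted p = 0.806 with an estimated correlation) did not pass without Tyro3-/-V1 replicate 2 (0.37) or Mertk-/-V2Tyro3-/-V2 replicate 2 or 3 (0.0542 and 0.215), or without the 2 libraries at the ends (0.224). The rod and microglia calls also ended with a filter of 50 (0.0511 and 0.112) or without members shared by lists (0.0579 and 0.0716). The rod call ended after TMM rescaling too (0.0548), and the microglia and mitochondrial calls after quantile normalization (0.113 and 0.069). With the retina covariate the respiratory chain and glycolysis calls ended too, and the glycolysis call also ended with the microglia covariate. The JAK-STAT3 list passed with a median of 0.01 and a mean of 0.38 (0.0105; adjusted p = 0.625 with an estimated correlation), and did not without Tyro3-/-V1 replicate 3 (0.132) or Mertk-/-V2Tyro3-/-V2 replicate 1 (0.154) or with the replicate block (0.0626).

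In this contrast 8 genes were higher and 19 lower with limma, and 2716 had an unadjusted p below 0.05. edgeR called 35 (13 higher, 22 lower) and DESeq2 692 (439 higher, 253 lower). Higher calls also outnumbered lower ones with array weights (1218 and 584), the replicate block (20 and 16) and without Mertk-/-V2Tyro3-/-V2 replicate 3 (18 and 11). The balance of directions therefore depended on the setting. The limma count was 5 without Tyro3-/-V1 replicate 1, 2 without its replicate 2 or 3, 9 without Mertk-/-V2Tyro3-/-V2 replicate 1, and 11 without the 2 libraries at the ends of the first component. Over the 6 fits that left out 1 library, Eif3j2 passed in 6, Rab37 and Eif3j1 in 4, Psd3 and Gchfr in 3, Ins2 and Ifit1 in 2, Rpe65, C4b, Sulf2, Sfrp5 and Sostdc1 in 1, and Cmpk2 and Kcnab1 in 0. Of 35 lists 9 were higher and 6 lower, and 0 passed with an estimated correlation (2 unadjusted) or with fry (8 unadjusted). Of 217 genes near Tyro3, 6 passed (Fisher's exact p = 4.35e-07).

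Against C57BL/6, both mutant groups shared 1 gene higher, Mzt1, and 1 lower, Tyro3, in contrasts that use the same controls. The log2 fold changes correlated across genes at 0.46, beside 0.50 in 100 simulations of unchanged groups against the same controls; genes are not independent replicates. Of the 103 genes called in the libraries labelled Mertk-/-V2Tyro3-/-V2, 17 also passed in the direct contrast of the mutant groups. Both contrasts use the same libraries labelled Mertk-/-V2Tyro3-/-V2, so those 17 are no independent support. Against the same controls, 91 of the 103 had the same sign in Tyro3-/-V1. Sharing controls raises such agreement by itself, so this count is no support for a shared change. Over the 103 genes, the median signed log2 fold change in Tyro3-/-V1 was 0.27, beside a median absolute 0.98 in the libraries labelled Mertk-/-V2Tyro3-/-V2.

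Itgb5-/- against WT129 asks what loss of the integrin chain changes. Beside Itgb5, B4galt4, a galactosyltransferase on chromosome 16 (38742264 to 38769049), rose from 283 ± 9.65 to 883 ± 2.38 normalized counts (SD, n = 3 each; log2 1.64 ± 0.12, adjusted p = 0.0111), and Hmgn2, a nucleosome-binding protein, from 958 ± 94.2 to 2902 ± 296 (1.60 ± 0.13, adjusted p = 0.0123). C1s1, a protease of the classical complement pathway, had 0 reads in all 3 Itgb5-/- libraries and 77.8 ± 33.5 normalized counts in WT129 (SD, n = 3), at least 80.7-fold lower against a floor of 3 reads over the group (limma adjusted p = 0.0176). It did not pass with edgeR (adjusted p = 0.11) or without Itgb5-/- replicate 1, 2 or 3 (0.111, 0.136 and 0.2), and over all alternatives the adjusted p ranged up to 0.362. Rps3a3 (log2 −3.59 ± 0.22, adjusted p = 0.00714) and Rps3a2 (−2.07 ± 0.19, adjusted p = 0.0221), copies of a ribosomal protein gene, fell, while their parent gene Rps3a1 stood at 8234 ± 1344 beside 2498 ± 560. Gm42047, named after its values were seen, had 0 counts in WT129 and 175.7 ± 87.5 in Itgb5-/-.

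Photoreceptor and retinal neuron transcripts were lower in Itgb5-/- libraries. Of 28 rod markers 0 passed with limma over all genes and 26 were lower adjusted over the list alone, with a median of −1.46 (camera adjusted p = 5.26e-23; adjusted p = 0.852 with an estimated correlation). Pdc, a phototransduction regulator, stood at −1.70 ± 0.32 (adjusted p = 0.256) and Rp1, a protein of the outer segment axoneme, at −1.24 ± 0.23 (adjusted p = 0.256). Inner retinal (−1.08, 1.18e-08) and cone markers (−0.72, 3.9e-05) and glycolysis genes (−0.14, 0.0217) were also lower, each with adjusted p = 0.852 with an estimated correlation. WT129 replicate 2 had the highest scores of the 6 libraries for rod (13.5) and inner retinal markers (9.71).

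Higher lists, each with adjusted p = 0.852 with an estimated correlation, were cholesterol synthesis (0.26, 0.000102), cell cycle (0.32, 0.000218), cytokines and chemokines (0.32, 0.0186), endothelial markers (0.27, 0.0217), the unfolded protein response (0.20, 0.0219), erythroid markers (0.54, 0.0219), lymphocyte and granulocyte markers (0.97, 0.025), microglia markers (0.23, 0.0305) and the JAK-STAT3 list (0.13, 0.0485). S100a9, a granulocyte protein, stood at log2 2.69 ± 0.60 (adjusted p = 0.353). Of these and the lower lists, rod, cone and inner retinal markers and cholesterol synthesis passed without each library in turn. With the neural retina score as a covariate, only rod markers passed in the same direction, and cholesterol synthesis had a median of −0.04 (camera adjusted p = 0.421). That score is built from the rod, cone and inner retinal lists. Without WT129 replicate 1, microglia (0.0523), endothelial (0.241), erythroid (0.0903) and glycolysis genes (0.0617) did not pass. Without WT129 replicate 2, cell cycle (0.275), microglia (0.493), endothelial (0.0879), cytokine (0.216), JAK-STAT3 (0.572), unfolded protein (0.0728) and glycolysis genes (0.493) did not. Without WT129 replicate 3, lymphocyte (0.125), erythroid (0.0779), cytokine (0.0779), JAK-STAT3 (0.106) and unfolded protein genes (0.224) did not. Without Itgb5-/- replicate 1, microglia (0.895), lymphocyte (0.0754), endothelial (0.764), erythroid (0.441), JAK-STAT3 (0.142) and glycolysis genes (0.0541) did not. Lymphocyte and JAK-STAT3 genes did not pass without Itgb5-/- replicate 2 (0.0945 and 0.0592) or 3 (0.217 and 0.0538), unfolded protein genes without replicate 2 (0.168), and glycolysis genes without replicate 3 (0.0538). Other settings ended calls too: no filter for JAK-STAT3 (0.0855), lymphocyte (0.0968), microglia (0.0736) and unfolded protein genes (0.0736), a filter of 50 for JAK-STAT3 (0.0608), erythroid (0.0741) and microglia genes (0.0827), quantile normalization for JAK-STAT3 (0.0562) and unfolded protein genes (0.075), and array weights for these 2 (0.213 and 0.0829), cytokine (0.053), endothelial (0.198), erythroid (0.113) and microglia genes (0.518). The replicate block ended the JAK-STAT3 call, and the term for sex the JAK-STAT3 and glycolysis calls. Leaving out members shared by lists ended the JAK-STAT3 and microglia calls. The interferon list did not pass (median 0.05 and mean 0.02, camera direction lower, adjusted p = 0.982), nor did complement (median 0.13, mean −0.50, camera direction lower, 0.315).

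With limma 3 genes were higher and 4 lower of 18653 tested, and 1544 had an unadjusted p below 0.05; edgeR called 5 and DESeq2 429. The limma count was 10 without WT129 replicate 2 and 0 without any other library. The unadjusted counts were then 2622 and 1801 without WT129 replicate 1 or 3, and 1193, 889 and 897 without Itgb5-/- replicate 1, 2 or 3; edgeR and DESeq2 were not run on those subsets. A term for sex, read from Xist and Ddx3y, gave 0 (limma, 1340 unadjusted), and the neural retina score as a covariate gave 1. By Xist and Ddx3y, WT129 replicate 3 and Itgb5-/- replicates 2 and 3 were female, so sex was not balanced between the groups. The other results of this comparison are not corrected for it. Of 35 lists 9 were higher and 4 lower, 8 passed without WT129 replicate 2, and 0 passed with an estimated correlation (0 unadjusted) or with fry (2 unadjusted). Of 131 genes within 10 Mb of Itgb5, 1 passed, B4galt4 (Fisher's exact p = 0.0414, Benjamini-Hochberg 0.0994).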

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

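No test in this part was chosen after the result was seen. In C57BL/6, the group with 6 libraries, each value was examined for a library whose gap to its nearest neighbour, divided by the whole range, was above Dixon's 95% critical value for 6 samples. Of 131 values examined 7 were above it, where 6.6 would be by chance. No biological explanation was tested.

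C57BL/6 replicate 4 stood apart in 4 of them. Its score for melanocyte and Schwann cell markers was 10.25 beside a mean of 9.27 in the other 5 (ratio 0.628). Its complement score was 8.24 beside 7.70 (ratio 0.667). Its score for sex-linked transcripts was 7.95 beside 8.30 (ratio 0.797). Its count of Ctss, a lysosomal protease of macrophages, was 481 beside 358 (ratio 0.696). Replicate 5 had 39.3 normalized counts of Ffar2 beside 107 (ratio 0.681). Replicate 6 had 56.5 of Ptprc, a leukocyte surface phosphatase, beside 80.5 (ratio 0.737). Replicate 1 had 31.7 of Eif3j2 beside 63.1 (ratio 0.665).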

How the results depend on the processing

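The covariates, the term for sex and leaving out the 2 libraries at the ends of the first component were chosen after the results were seen. Pseudocounts, TMM rescaling, the filter of 50 and edgeR kept every count of genes within 1.5 times its value. For named genes over all alternatives, 2960 values kept their direction and their side of the threshold, 533 lost the threshold and 135 gained it. For lists 1080 kept both, 234 lost the threshold and 18 changed sign. Where nothing else is said, the cause was not tested. Counts of genes follow in the order of the libraries labelled Mertk-/-V2Tyro3-/-V2 against C57BL/6 (103), Tyro3-/-V1 against C57BL/6 (9), the mutant groups against each other (27) and Itgb5-/- against WT129 (7), with a comparison left out where its count stayed within 1.5 times.

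DESeq2 gave 1725, 131, 692 and 429. Array weights gave 582, 4354, 1802 and 13, with a fit that did not converge in the first table. Treating replicate numbers as a block gave 716 for the first comparison and 0 for Itgb5-/- (limma, 1146 unadjusted); the numbers do not pair the libraries by the labels, and 6 of 9 pairs in the first table and 1 of 3 in the second resembled their own number most. Quantile normalization gave 27, no term for the mark 53, the marked libraries alone 11, and an absolute log2 fold change of at least 1 gave 50, all for the first comparison. Only the compared groups gave 29 for the first and 2 for the third, from fewer libraries. No filter gave 41 for the third and 19 for Itgb5-/-. The retina covariate gave 33, 15, 43 and 1, and the ocular surface covariate 20 for the second and 215 for the third. The microglia covariate gave 0 (limma, 2844 unadjusted) for the first and 14 for the third. Without the 2 libraries at the ends the counts were 13, 5 and 11 in the first table, and the term for sex gave 0 (1340 unadjusted) in Itgb5-/-. Leaving out each library gave 0 to 142, 3 to 9, 2 to 35 and 0 to 10.

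Lists past the threshold numbered 17, 11, 15 and 13, and 0 in each comparison with an estimated correlation; fry gave 3, 0, 0 and 0. For Tyro3-/-V1, no term for the mark and the ocular surface covariate each gave 18. For Itgb5-/-, array weights gave 8 and the retina covariate 7. Leaving out each library gave 16 to 19, 10 to 19, 13 to 17 and 8 to 12.

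Tyro3 in the libraries labelled Mertk-/-V2Tyro3-/-V2 kept its fall at −1.26 with the microglia covariate but not the threshold (adjusted p = 0.131, the highest of its alternatives; the lowest was 7.55e-14), and ranged from −1.24 to −1.04 over the libraries left out, with adjusted p = 0.0605 and 0.0599 without C57BL/6 replicate 1 or 2. Itgb5 in Itgb5-/- was −1.58 with the block (adjusted p = 0.16), −1.37 with the retina covariate (0.362, the highest; the lowest was 7.79e-17) and −1.50 with the term for sex (0.0723), and ranged from −1.71 to −1.47 over the libraries left out. Array weights took Itgb5 in Tyro3-/-V1 past the threshold at −0.19 (adjusted p = 0.032) and Tyro3 between the mutant groups at 0.60 (0.00633). Over the libraries left out, the other ranges were −1.63 to −1.48 for Tyro3 in Tyro3-/-V1, 0.31 to 0.51 for Tyro3 between the mutant groups and 0.10 to 0.45 for it in Itgb5-/-. For Mertk they were −0.21 to 0.05, −0.23 to 0.15, −0.21 to 0.16 and −0.14 to 0.24 in the order of the comparisons, and for Itgb5 −0.17 to −0.06, −0.25 to −0.13 and 0 to 0.13 in the first table.

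Some lists changed sign. In the libraries labelled Mertk-/-V2Tyro3-/-V2 against C57BL/6, rod markers had medians of 0.07 with no term for the mark, where the test turned, −0.34 with the retina covariate and −0.14 without the 2 libraries at the ends, and the NRF2 list 0 with the retina covariate. Against Tyro3-/-V1, rod markers had −0.52 with the retina covariate and −0.06 without the 2 libraries at the ends or without Mertk-/-V2Tyro3-/-V2 replicate 3 (up to 0.74 over the libraries left out), and the respiratory chain 0.01 with array weights. In Tyro3-/-V1 with no term for the mark, erythroid markers had 0.11 and mitochondrial transcripts −0.01. In Itgb5-/-, microglia markers had 0.02 without Itgb5-/- replicate 1 (up to 0.40 over the libraries left out) and −0.28 with the retina covariate, which also gave 0.17 for cone and 0.31 for inner retinal markers, −0.03 for endothelial markers, −0.07 for the JAK-STAT3 list, −0.04 for cholesterol synthesis and 0.12 for glycolysis. A covariate built from a list removes that list's own difference by construction. The correlation between the mutant groups' changes was 0.07 with no term for the mark and had a median of −0.09 (−0.53 to 0.16) over 20 splits of C57BL/6 into separate controls for each group. Near Mertk, a window of 5 Mb held 1 call in Tyro3-/-V1 (Fisher's exact p = 0.0518) and 0 between the mutant groups (limma; exact p = 1), and near Itgb5 a window of 20 Mb held 1 (exact p = 0.0978). Depth limits the genes near the filter, and in simulated data 35 to 57 of 100 genes changed 2-fold were recovered.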

Other observations

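The marker lists for lens, ocular surface and muscle, the tests of explanations for the interferon, visual cycle and chromosome 2 patterns, the comparison with WT129 and the list of genes that differ by the mark 23 were chosen after the results were seen; the counts over other splits of the samples were planned. The groups, the models, the gene lists and the rule for naming genes were chosen before the data were examined.

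Tissue next to the RPE varied between the libraries. Lens markers scored 13.53 ± 1.18 (SD, n = 3) in the libraries labelled Mertk-/-V2Tyro3-/-V2 and 11.26 ± 1.31 in C57BL/6 (SD, n = 6), a difference of 2.26 (exact permutation p = 0.0238, Benjamini-Hochberg 0.151; higher in 3 of 3 libraries). Ocular surface epithelium markers had medians of −1.38 in the libraries labelled Mertk-/-V2Tyro3-/-V2 and −0.65 in Tyro3-/-V1 against C57BL/6, and striated muscle markers −1.60 and −0.24. In Itgb5-/- against WT129 these medians were 0.23 for lens, 0.45 for ocular surface and 1.36 for muscle.

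Within C57BL/6, 33 genes were higher in the 3 libraries without the mark 23 and 0 were lower (limma, 4733 at an unadjusted p below 0.05; edgeR and DESeq2 were not run on this contrast). They included 5 mitochondrial transcripts and 23 gene models. Over all 6 C57BL/6 libraries and without the model, the interferon score differed by 1.00, complement by 0.61, microglia by 0.51, matrix genes by 0.25 and histones by −0.49 in the libraries labelled Mertk-/-V2Tyro3-/-V2. Each had an exact permutation p of 0.0119, the smallest that 84 splits can give (Benjamini-Hochberg 0.0904), and all 3 libraries lay on one side. Interferon gamma (0.48) and JAK-STAT3 genes (0.44) had an exact permutation p of 0.0357 (Benjamini-Hochberg 0.17), RPE identity (−0.20) and phagocytosis genes (−0.07) 0.0476 (Benjamini-Hochberg 0.181), and visual cycle (−0.22) and fibroblast genes (0.21) 0.0595 (Benjamini-Hochberg 0.188). No list passed this test after the Benjamini-Hochberg adjustment, and visual cycle and fibroblast genes did not pass it unadjusted. Nor did the other lists past the camera test. Their exact permutation p was 0.9762 for rod (0.07), 0.3095 for cone (0.67), 0.4524 for inner retinal (0.56) and 0.3333 for endothelial markers (0.33). It was 0.5119 for cell cycle (−0.41), 0.75 for unfolded protein (−0.03), 0.369 for fatty acid oxidation (−0.10) and 0.4881 for respiratory chain (−0.06) and NRF2 genes (−0.10).

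Interferon-induced transcripts were higher in the libraries labelled Mertk-/-V2Tyro3-/-V2 than in C57BL/6, with adjusted p = 0.628 for the list with an estimated correlation. Several forms of the tests per library were run; those given are two-sided exact permutations of 3 against 6 libraries, repeated without each library, beside differences from a fit with the term for the mark. Where a covariate is used, its slope within groups was estimated first and taken out. That slope was kept fixed in the permutations and repeats, so p is exact only for that slope and leaves out its error. Within groups the interferon score fell as the retina score rose (slope −0.37 ± 0.11, SE). If that slope holds between groups, it argues against more neural retina in those samples as the whole cause. With the slope taken out, the interferon score was higher by 1.30 ± 0.20 (SE) in the fit with the term for the mark. With the slope estimated anew without each library in turn, that difference was 1.07 to 1.44. Over all 6 C57BL/6 libraries the difference was 1.16 (exact permutation p = 0.0119, at most 0.0357 with a library left out). Against the 3 marked libraries alone the exact permutation p was 0.1, the smallest possible. A negative slope could only widen the gap for libraries with more retina. The exact permutation p was already 0.0119 before the slope was taken out, so the permutation adds no support. With the retina score as a covariate the list's median was 1.23 (camera adjusted p = 1.72e-31, adjusted p = 0.0957 with an estimated correlation, fry adjusted p = 0.00417). More microglia and macrophages stay open. The interferon score minus the microglia score differed by 0.48 ± 0.32 in the fit and by 0.49 over all 6 C57BL/6 libraries (exact permutation p = 0.0952). Centred on C57BL/6 it was 1.08, 0.65 and −0.26 in replicates 1 to 3. With the microglia score as a covariate the list's median was 1.01 (camera adjusted p = 9.93e-13, adjusted p = 0.555 with an estimated correlation). The interferon score was then higher by 1.13 ± 0.37 in the fit and by 1.28 over all 6 C57BL/6 libraries (exact permutation p = 0.0119). But the slope of −0.55 ± 0.64 was too imprecise to correct with. That explanation and an interferon response tied to the genotype, which may include infection or housing, cannot be told apart with 3 libraries. The genotype itself was not tested apart from the animals that carried it.

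Visual cycle transcripts were lower in the same libraries, with adjusted p = 0.628 for the list with an estimated correlation and 0.0688 with fry. With the retina score as a covariate the list's median was −0.41 beside −0.59 (camera adjusted p = 0.000293; adjusted p = 0.454 with an estimated correlation). The score per library was then lower by −0.33 ± 0.12 (SE) in the fit with the term for the mark. Over all 6 C57BL/6 libraries the difference was −0.23 (exact permutation p = 0.0476). This exact p was 0.05 or more in 8 of 9 repeats that left out 1 library, up to 0.1071, so more neural retina stays open. A lower share of RPE could lower these genes together with melanin genes, whose median was 0.23. The visual cycle score minus the melanin score had a mean of −0.19 in the libraries labelled Mertk-/-V2Tyro3-/-V2, each of them below the 3 marked C57BL/6 libraries, whose mean was 0.26. The difference with the term for the mark was −0.45 ± 0.15 (SE), and −0.61 to −0.31 with 1 library left out. This goes against a lower share only if melanin genes follow that share, which was not tested. Against the marked libraries alone the exact permutation p was 0.1, the smallest that 3 against 3 can give, and over all 6 C57BL/6 libraries the difference was −0.32 (exact permutation p = 0.0833). A lower RPE share and a lower expression per cell therefore cannot be told apart by these values. The exact permutation cannot go below 0.1 with 3 marked controls, and the other 3 differ by the mark.

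In Tyro3-/-V1, genes near Tyro3 differed from C57BL/6, and a candidate explanation is chromosome 2 sequence of another strain carried with the allele (Fisher's exact p = 0.00331 within 10 Mb). The direction in WT129 was taken against C57BL/6 replicates 4 to 6, which the fold change of Tyro3-/-V1 does not use. Of the 13 genes near Tyro3 among the 50 of smallest p, 13 went the same way in WT129 as in Tyro3-/-V1 (exact sign test p = 0.000244). Of the other 37, 20 did (exact sign test p = 0.743), though strain, table and normalization differ together in that comparison. Among those 37 are genes past the threshold: Eif3j2, Gm3650, Pcna-ps2 and Tgm3 went the way of WT129, and Lum and Mzt1 did not. Eif3j1 had 949 normalized counts in C57BL/6 and 458 in WT129, and Eif3j2 57.9 and 350. Gatm had 66.4 normalized counts in C57BL/6 and 1180 in WT129, AA467197 201 and 26.1, and Tyro3 itself 3398 and 1778, so its level in Tyro3-/-V1 may hold a part due to strain. Loss of Tyro3 as the whole cause is argued against, unless loss of Mertk offsets it. Tyro3 is low in both mutant groups, yet 6 of 217 genes near it passed between them (Fisher's exact p = 4.35e-07, odds ratio 26). Both genes called near it in Tyro3-/-V1 were among these, Eif3j1 with −0.94 beside 0.05 in the libraries labelled Mertk-/-V2Tyro3-/-V2 and AA467197 with −4.64 beside −1.05, while Tyro3 kept 0.75 of its change there. Both genes were picked by their change in the same Tyro3-/-V1 libraries, so they are no independent support. Loss of Tyro3 as a part of the cause cannot be told apart from flanking sequence: the 13 genes had a signed median of 0.18 in the libraries labelled Mertk-/-V2Tyro3-/-V2, with 10 of 13 below 0.5 of the change (exact sign test p = 0.0923), and Bahd1 was lower by a similar amount in both groups (−0.54 and −0.47). For Eif3j1 and Eif3j2, the ratio of summed counts to C57BL/6 was 0.93 while the copies stood at 0.55 and 7.25, which is consistent with reads moved between near-identical copies.

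Other splits of the same libraries were counted. For the libraries labelled Mertk-/-V2Tyro3-/-V2 against marked C57BL/6, the 10 splits are too few for a share under 0.05: the real split called 103 genes and 17 lists, the highest other 0 and 15, and 1 split gave as many in each case. For Tyro3-/-V1 the 10 splits are too few as well: 9 genes and 11 lists against 0 and 16, with 1 and 7 splits as large. The direct contrast of the mutant groups gave 27 genes and 15 lists against 697 and 18, with 2 and 3 of 10 splits as large, and Itgb5-/- gave 7 and 13 against 1 and 18, with 1 and 5 of 10; these 10 are too few too.

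Without the term for the mark, 84 splits can be drawn. Of these, 3 gave as many genes as the 53 of the libraries labelled Mertk-/-V2Tyro3-/-V2 and 4 as many as the 12 of Tyro3-/-V1, a share under 0.05. These splits exchange libraries with and without the mark, which differed, so the share does not settle whether chance can be excluded. The split that follows the mark, C57BL/6 replicates 4 to 6 against the rest, called 106 and 26 genes, more than the real ones. With the marked libraries alone the counts were 11 and 7. The highest other splits called 5306 and 1690 genes and set C57BL/6 replicates 5 and 6 apart together with replicate 3 of the mutant group. In the direct contrast 697 genes parted Tyro3-/-V1 replicates 1 and 2 and Mertk-/-V2Tyro3-/-V2 replicate 1 from the other 3 libraries. Such counts point to a structure of the samples, and what it is was not tested. For lists, 5 splits gave as many as the 21 (highest other 22) and 12 as many as the 18 (highest other 23), so chance cannot be excluded.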
